A study of Mus musculus with 9 samples.

How the data were processed

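RNA from mouse tibialis anterior muscle collected after injury was sequenced by the authors in 9 libraries, 3 each from young wild-type mice of 4 to 6 months, old wild-type mice of 24 months and old P311-/- mice. The age of the P311-/- mice in months, the kind of injury and the time after injury are not given in the sources used here. The labels number the replicates 1 to 3 within each group and do not state whether each is a separate animal, so the p-values measure the spread between these libraries.

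The authors listed HISAT2 2.2.1, featureCounts 2.1.1 and DESeq2 1.42.0 among their tools and named the genome build mm39; the options are not given in the sources used here. The gene coordinates in the deposited table were those of GRCm38, because 53585 of 54495 gene identifiers shared with GENCODE M21 had identical positions there, a share of 98.3%. Positions are therefore given on GRCm38. The use of strand in counting is unknown, so values of overlapping or antisense genes, and of genes with close copies or pseudogenes, carry that uncertainty.

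The deposited values were FPKM, reads per gene length and library size, with the library size scaled by the authors, for 54532 genes. Deposited gene lengths, in bases, were used as the authors gave them, with no normalization. Multiplying each FPKM by the gene length and by 1 constant per library gave whole reads for 100% of the values within a tolerance of 0.001. The library sizes behind the deposited values were equal to median-of-ratios size factors multiplied by 1 constant, the same in all 9 libraries. Recovered reads per library ranged from 14222204 to 31910890. They served for depth, filters, alternative scalings and the fits with voom.

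The planned quasi-likelihood test of edgeR on raw counts with TMM factors was not run. The deposited unit is FPKM, and the recovered reads were not used for that test, although they could have been. The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust variance moderation, on log2 of FPKM plus a pseudocount of 0.1. A gene was tested if it had at least 0.5 FPKM in at least 3 libraries and at least 10 recovered reads in at least 3 libraries, which left 14233 genes. All 9 libraries entered 1 fit with group means and no block. Each of the 3 comparisons was adjusted by the Benjamini-Hochberg (BH) method, and an adjusted p under 0.05 counted as a call. Fold changes are on the scale of log2 of FPKM plus the pseudocount, which understates the change of low genes, and are first group over second, and the standard error (SE) is that of the log2 fold change. Standard deviations (SD) are of FPKM over the 3 libraries of a group.

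For each comparison, 33 gene lists of pathways and cell type markers were tested with camera of limma at a preset correlation between genes of 0.01, adjusted by BH over the lists. The same lists were tested with an estimated correlation and with fry, which tests whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Gene lists, tests, comparisons, alternatives and the rule for named genes were fixed before the data were examined, except where stated. The rule named Nrep and the 10 genes higher and 10 genes lower with the largest log2 fold change among calls with an average log2 CPM (counts per library size) of at least 1, no overlap between the groups and an established symbol. For old P311-/- against young wild type it took 5 in each direction. Where fewer than 5 passed in a direction it took the 5 with the smallest p. It added up to 4 members with the smallest p from each list that passed and from 5 lists always shown, and 10 genes always given. Other members of the lists are named as values.

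Sample structure was described by principal components and Euclidean distances over the tested genes. The excess of between-group over within-group distance was tested with a one-sided exact permutation test over the 10 splits of 6 libraries, whose smallest possible p is 0.1. The change of age-called genes in P311-/- muscle was compared with 100 simulations of groups without a difference, because the comparisons share libraries. Ranking the simulated genes by difference over noise, as calls are made, was chosen after the values were seen. Ranking by the difference alone had given opposite signs in 82.7% of genes in place of 90.4%. The covariance of the fold changes was also taken with separate old wild-type libraries in each comparison, in all 6 arrangements of 1 and 2, with and without P311-/- replicate 1, added after the data were seen.

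The method was tested on simulated data with 14233 genes, 100 of them changed at each of 2 sizes. It recovered 61%, 54% and 65% of 2-fold changes and 89%, 92% and 85% of 4-fold changes, in the order old against young wild type, old P311-/- against old wild type and old P311-/- against young wild type. The false share among its calls was 5.56%, 10.7% and 4.35%. The simulation drew genes independently, with the same spread for a gene in all 9 libraries. It held no library apart from its group, as P311-/- replicate 1 was, so these shares may not hold for the real libraries.

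The alternatives were total-count and upper-quartile scaling, no filter, a filter at 1 CPM, voom with library quality weights, fits of the 6 libraries compared, the replicate number as a block, a minimum fold of 2 and leaving out each library in turn. Pseudocounts of 1 and 0.01, TMM scaling, voom without weights, library weights on log2 FPKM and removal of a trend with GC content and gene length were added after the data were seen. GC content came from the GRCm38 reference and was available for 14219 of the 14233 genes. No library or column was left out. Lists, matched random sets and figures were computed with R and with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.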

Results

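RNA was sequenced from injured tibialis anterior muscle, a hind limb muscle, of 3 groups of mice. There were 3 libraries each from young wild-type, old wild-type and old P311-/- mice, in which the gene for P311 (symbol Nrep) was deleted. Recovered reads numbered 14222204, 15514343 and 18249081 in the young wild-type libraries. They were 22528289, 17730208 and 23133027 in the old wild-type libraries and 25652596, 20475248 and 31910890 in the old P311-/- libraries. The share of reads from mitochondrial genes was 8.79% to 10.7% in young wild type, 13.2% to 17.6% in old wild type and 9.47% to 14.1% in old P311-/-. The share from ribosomal RNA genes was 1.01% to 1.15% in young wild type, 0.407% to 0.5998% in old wild type and 0.458% to 1.05% in old P311-/-. Transcripts of the Y-linked gene Ddx3y stood at 13.9 to 28.1 FPKM and Xist at no more than 0.0148 FPKM in all 9 libraries.

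Nrep (ENSMUSG00000042834, chromosome 18, 33437019 to 33464029, GRCm38), the gene deleted in the knockout, was lower in all 3 P311-/- libraries than in any wild-type library. Its level was 74.3 ± 11.3 FPKM (SD, n = 3) in young wild type, 75.6 ± 6.51 FPKM (SD, n = 3) in old wild type and 10.3 ± 4.26 FPKM (SD, n = 3) in old P311-/-. The P311-/- mean was 13.6% of the old wild-type mean, and 1062, 286 and 738 reads of the gene remained in the 3 knockout libraries. Against old wild type the log2 fold change was -2.94 (SE 0.26, limma adjusted p = 0.00364), and against young wild type it was -2.91 (adjusted p = 0.00404). Between old and young wild type the difference of 0.03 on the log2 scale (SE 0.26) did not pass (adjusted p = 0.949).

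**Figure D1:**
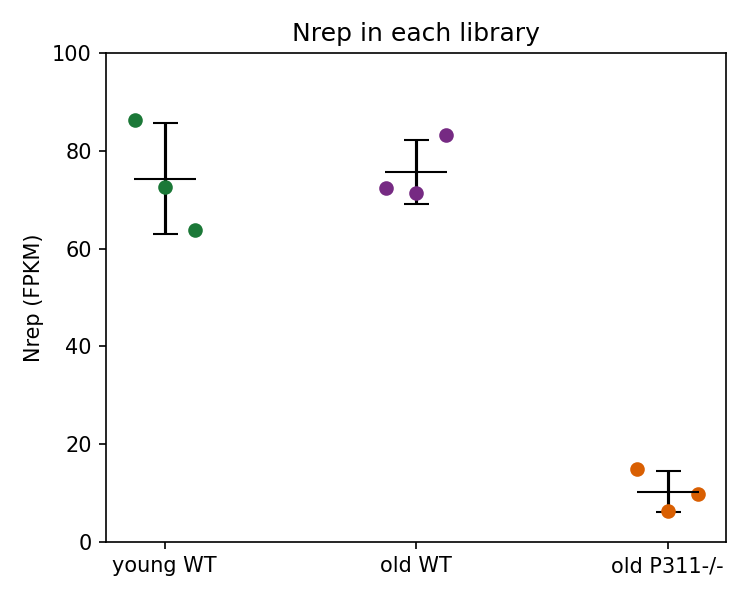
FPKM of Nrep in each of the 9 libraries (points), with the mean and SD of each group of 3. The 3 old P311-/- libraries lie between 6.37 and 14.8 FPKM, and the 6 wild-type libraries between 63.9 and 86.3 FPKM.

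The first principal component held 30.2% of the variance and the second 23.2%. Old P311-/- replicates 2 and 3 lay at 52.3 and 37.9 on the first component, and replicate 1 of the same group at -11.2, nearer to the wild-type libraries. Log2 values of replicates correlated, across genes, at 0.963 to 0.966 in young wild type, 0.968 to 0.972 in old wild type and 0.945 to 0.967 in old P311-/-, and genes are not independent replicates. Distances between groups exceeded those within groups by 17.0 for old against young wild type (exact permutation p = 0.1), 7.66 for old P311-/- against old wild type (exact p = 0.3) and 12.6 for old P311-/- against young wild type (exact p = 0.1). The smallest p that 3 libraries against 3 allow is 0.1. The mean distance was 78.2 among the P311-/- libraries, 61.9 among the old wild-type libraries and 77.7 between these groups. On average the P311-/- libraries were thus no nearer to each other than to old wild type. This came from replicate 1, which lay at 86.0 and 81.9 from replicates 2 and 3 and at 59.6 to 70.0 from the old wild-type libraries. Replicates 2 and 3 lay at 66.7 from each other and at 78.6 to 90.6 from the old wild-type libraries.

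**Figure D2:**
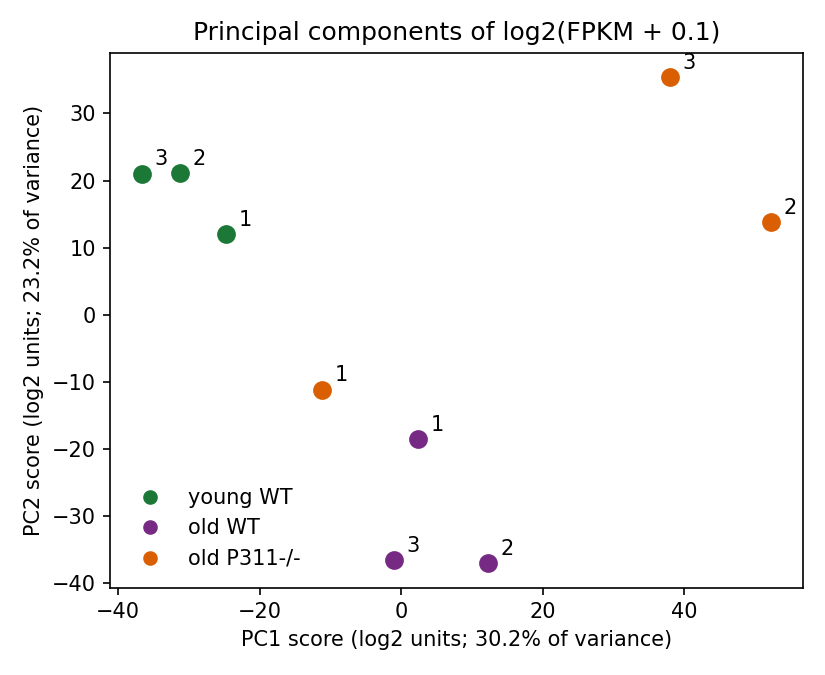
Principal components 1 (30.2% of the variance) and 2 (23.2%) of log2 FPKM over 14233 genes, 1 point per library. Old P311-/- replicate 1 lies at -11.2 on the first component and replicates 2 and 3 at 52.3 and 37.9.

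The comparison of old with young wild type asks how injured muscle differs with age. As lists, genes of the ribosome and of the respiratory chain were higher in old muscle and matrix genes lower by camera, with 21 of 74, 15 of 75 and 4 of 37 members passing on their own. With an estimated correlation none of these lists passed (adjusted p = 0.956, 0.956 and 0.982). Sln, which encodes sarcolipin, an inhibitor of the calcium pump of the sarcoplasmic reticulum, stood at 278 ± 127 FPKM (SD, n = 3) in old and 42.8 ± 5.46 FPKM (SD, n = 3) in young muscle. Retnla, a gene of alternatively activated macrophages, stood at 69.5 ± 17.8 against 13.2 ± 15.5 FPKM (SD, n = 3). Col1a1, a chain of type I collagen, stood at 198 ± 26.8 FPKM (SD, n = 3) in old and 408 ± 42.8 FPKM (SD, n = 3) in young muscle. Cd5l, a secreted macrophage protein, stood at 0.345 ± 0.0181 in old against 4.28 ± 2.28 FPKM (SD, n = 3) in young muscle.

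With limma, 768 of 14233 genes passed, 482 higher and 286 lower in old muscle, and 219 of them changed at least 2-fold. The values of the groups did not overlap for 37.1% of genes, where chance gives 10% on average over splits. Genes vary together, so a single split can lie well above or below that average. The count fell to 14, 1 and 0 without young replicates 1, 2 and 3, to 0 and 10 without old replicates 2 and 3 (2741 and 2737 genes at an unadjusted p under 0.05 in the fits with 0) and to 435 without P311-/- replicate 3, rose to 1755 without P311-/- replicate 1, and no gene passed in every such fit (739 of the 768 had an adjusted p above 0.03). It was 346 under total-count scaling (27.7% of them higher, against 62.8%), 5 with no filter, 13 with a trend with GC content and gene length removed, 1653 in a fit of the 6 libraries and 3001 with voom and library quality weights (1005 with voom alone and 2290 with library weights alone).

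Among the genes with the largest increases, Sln rose by 2.57 on the log2 scale (SE 0.37, adjusted p = 0.0287), Retnla by 3.04 (SE 0.65, adjusted p = 0.0366) and Fcer1a, a subunit of the IgE receptor of mast cells, by 2.31 (SE 0.43, adjusted p = 0.0308). Dbp, a transcription factor under control of the circadian clock, rose from 6.34 ± 2.13 to 23.9 ± 9.34 FPKM (SD, n = 3). Dkk3, which encodes a secreted protein, rose by 1.85 on the log2 scale. The mitochondrial genes mt-Tn, mt-Tc, mt-Co3 and mt-Co2 rose by 3.99, 3.32, 2.54 and 2.16 on the log2 scale, and mitochondrial sequences have nuclear copies. Rps27a, a ribosomal protein gene with processed copies, rose from 46.0 ± 12.3 to 169 ± 23.9 FPKM (SD, n = 3).

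Among the largest decreases, Cd5l fell by 3.13 on the log2 scale (SE 0.60, adjusted p = 0.0308). Malat1, a nuclear long non-coding RNA, fell from 182 ± 40.6 to 69.3 ± 16.9 FPKM (SD, n = 3), and Eln, which encodes elastin, from 15.1 ± 3.72 to 5.83 ± 1.08 FPKM (SD, n = 3). The others were Efcc1 (log2 fold change -1.75), Igf2bp2, an RNA-binding protein (-1.57), Igsf9b (-1.56), Islr2 (-1.53), Tlr5, the receptor of flagellin (-1.49), the kinase gene Hipk2 (-1.47) and the antisense transcript Irx3os (-1.47). Islr2 overlaps Islr, which also fell, and the strand setting of the counts is unknown.

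Of 75 measured nuclear genes of oxidative phosphorylation, 15 rose over all genes tested and 35 rose adjusted over the list alone, and none fell. The median log2 fold change was 0.43, with 74 of 75 members above 0, and the list passed camera (adjusted p = 7.01e-16; adjusted p = 0.956 with an estimated correlation). Uqcrb, a subunit of complex III, rose from 191 ± 13.8 to 392 ± 66.3 FPKM (SD, n = 3), and the complex I genes Ndufa5 and Ndufs4 rose by 1.02 and 0.93 on the log2 scale. Of 13 mitochondrially encoded members, 2 rose and 6 rose adjusted over the list alone (median 0.83, camera adjusted p = 5.38e-05; adjusted p = 0.956 with an estimated correlation). With the trend with GC content and gene length removed, that list had a median of 0.11 and an adjusted p of 0.249. Among 26 genes of fatty acid oxidation, 2 rose over all genes and 2 adjusted over the list alone (median 0.28, camera adjusted p = 0.00206; adjusted p = 0.991 with an estimated correlation). These were Cd36, a fatty acid transporter, from 47.6 ± 6.56 to 98.9 ± 11.6 FPKM (SD, n = 3), and Etfa, with a log2 fold change of 0.60.

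Of 74 ribosomal protein genes, 21 rose over all genes and 38 adjusted over the list alone, and none fell. The median was 0.43 (camera adjusted p = 1.58e-14; adjusted p = 0.956 with an estimated correlation), and fry also passed (adjusted p = 0.0330). Rpl39 rose by 1.25, Rps24 by 0.81 and Rpl22 by 0.74 on the log2 scale. Shorter genes and genes of lower GC content tended to be higher in old muscle, with Spearman correlations across 14219 genes of -0.25 for length and -0.36 for GC content, and genes are not independent replicates. The genes called higher had a median length of 2352 bases and those called lower 6392 bases. Among 15 markers of dendritic and mast cells, 2 rose over all genes and 3 adjusted over the list alone (median 0.58, camera adjusted p = 0.0165; adjusted p = 0.956 with an estimated correlation). They included Fcer1a and the mast cell protease gene Cpa3, with a log2 fold change of 1.64.

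Of 37 extracellular matrix genes, 4 fell over all genes and 17 adjusted over the list alone, none rose, and all 37 had a log2 fold change below 0. The median was -0.64 (camera adjusted p = 2.09e-09; adjusted p = 0.982 with an estimated correlation). Col1a1 fell by 1.04 on the log2 scale (SE 0.24, adjusted p = 0.0436), Eln by 1.35, Adamts2, which trims procollagen, by 1.04, and Serpinh1, a collagen chaperone, from 144 ± 8.71 to 72.2 ± 11.5 FPKM (SD, n = 3). Of 20 markers of fibro-adipogenic progenitors and fibroblasts, 4 fell over all genes and 9 adjusted over the list alone (median -0.48, camera adjusted p = 5.38e-05; adjusted p = 0.956 with an estimated correlation). The 4 were Fbn1, Islr, Cd248 and Osr1. Among 25 genes of the TGF-beta pathway, 1 fell over all genes and 2 adjusted over the list alone (median -0.25, camera adjusted p = 0.0165; adjusted p = 0.956 with an estimated correlation). The 1 was Ski, a repressor of SMAD signalling, with a log2 fold change of -0.47. That list did not pass without young replicate 2 (adjusted p = 0.0710) or with the trend with GC content and gene length removed (adjusted p = 0.204). The lists of complement (17 genes, median -0.41, camera adjusted p = 0.0165) and interferon response (37 genes, median -0.40, adjusted p = 0.0416) passed with 0 members called by limma, over all genes or adjusted over the list alone (5 and 3 at an unadjusted p under 0.05), and each had an adjusted p of 0.991 with an estimated correlation. Complement did not pass without old replicate 2 (adjusted p = 0.126) or 3 (0.0823), nor interferon response without young replicate 1 (0.154) or old replicate 2 (0.147) or 3 (0.352). Under total-count scaling their adjusted p was 0.0539 and 0.285.

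The lists for muscle stem cells and new fibres did not pass. Satellite cell genes had a median of -0.02 (17 genes, camera adjusted p = 0.614), myogenic differentiation genes -0.03 (21 genes, adjusted p = 0.979) and embryonic fibre genes 0.29 (12 genes, adjusted p = 0.410). In these lists 1 myogenic gene and 1 embryonic fibre gene rose over all genes, and as many adjusted over the list alone. These were Mef2a, a muscle transcription factor, with a log2 fold change of 0.55 (SE 0.12), and Chrna1, a subunit of the acetylcholine receptor, from 13.4 ± 2.47 to 43.7 ± 20.5 FPKM (SD, n = 3). Pax7, the satellite cell factor, had a log2 fold change of -0.59 (adjusted p = 0.160). Myod1 had -0.23 (adjusted p = 0.476), Myog -0.39 (0.575), the embryonic myosin Myh3 -0.79 (0.312) and the fast myosin Myh4 -0.02 (0.963). Tgfb1, Tgfb2 and Tgfb3 had -0.18, -0.37 and -0.34, and the macrophage gene Adgre1 had -0.80 (adjusted p = 0.139), and none of these passed. The median and mean differed in sign for fast fibre genes (0.13 and -0.01) and cytokines (-0.16 and 0.01), and the test of senescence genes pointed down beside a median of 0.06; none of these lists passed.

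**Figure D3:**
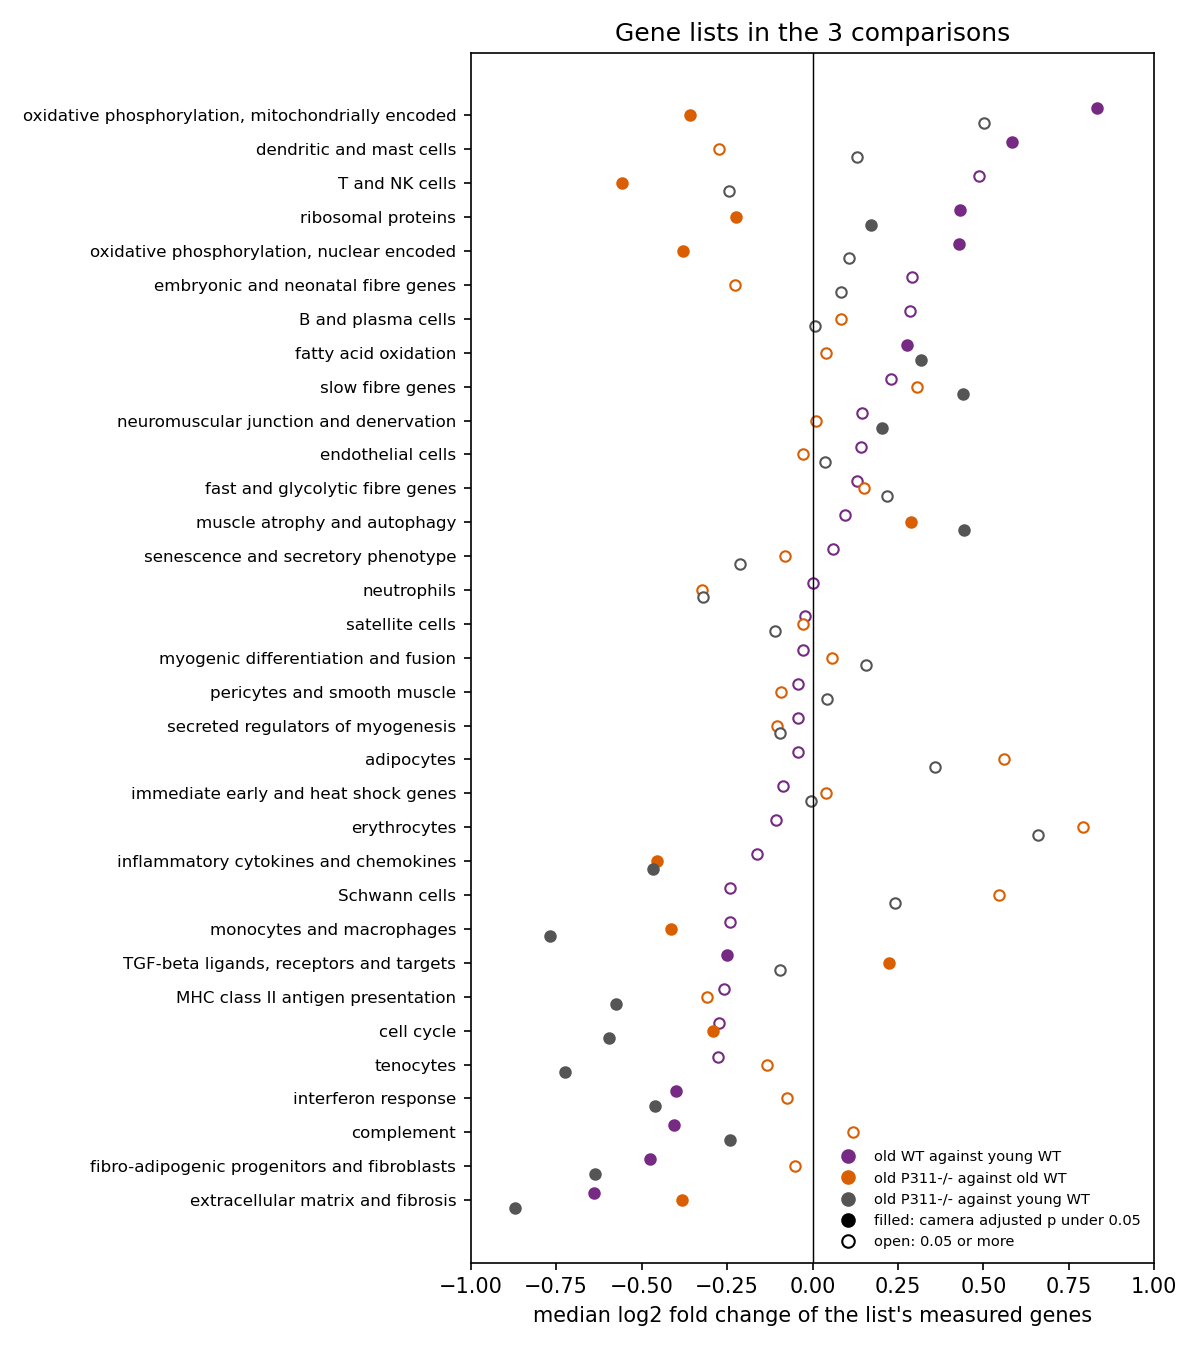
Median log2 fold change of each gene list in the 3 comparisons, with filled marks for lists that passed camera at an adjusted p under 0.05. Nuclear oxidative phosphorylation genes stand at 0.43 in old against young wild type and -0.38 in old P311-/- against old wild type. Both comparisons share the old wild-type libraries, with opposite sign, and the list passed in neither with an estimated correlation.

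Old P311-/- muscle was compared with old wild type to ask what the loss of P311 changes at old age. Beside Nrep, the DNA-binding protein gene Hmgb1 (ENSMUSG00000066551, chromosome 5, 149046702 to 149184489) stood at 5.93 ± 0.264 FPKM (SD, n = 3) in P311-/- and 16.9 ± 2.32 FPKM (SD, n = 3) in old wild type. Klra7 (ENSMUSG00000067599, chromosome 6, 130218605 to 130233322), a receptor of natural killer cells, stood at 0.564 ± 0.0890 against 2.78 ± 0.573 FPKM (SD, n = 3). Btaf1 (ENSMUSG00000040565, chromosome 19, 36926079 to 37012752), a regulator of the TATA-binding protein, stood at 2.77 ± 0.340 against 5.97 ± 0.644 FPKM (SD, n = 3). The pseudogene Tmem181b-ps (ENSMUSG00000096780, chromosome 17, 6438524 to 6467022) was higher, at 4.37 ± 0.111 against 1.49 ± 0.118 FPKM (SD, n = 3). Genes of the respiratory chain, the ribosome and the matrix were lower as lists by camera, with no single member passing over all genes (38, 27 and 3 at an unadjusted p under 0.05). With an estimated correlation none of these lists passed (adjusted p = 0.902 for each), and fry passed none.

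With limma, 10 of 14233 genes passed, 2 higher and 8 lower, and all 10 changed at least 2-fold. The values of the groups did not overlap for 18.04% of genes, where chance gives 10% on average over splits. Genes vary together, so a single split can lie well above or below that average. At an unadjusted p under 0.05 there were 2296 genes, fewer than the 2476 and 2704 given by other splits of these 6 libraries. In both of those splits P311-/- replicates 2 and 3 lay together and apart from replicate 1. Hmgb1 fell by 1.49 (SE 0.13, adjusted p = 0.00364), Klra7 by 2.103 (adjusted p = 0.00769) and Btaf1 by 1.08 (adjusted p = 0.0244) on the log2 scale, and Tmem181b-ps rose by 1.49 (adjusted p = 0.00516). The other 5 calls were outside the rule for named genes and were chosen after their values were seen. Gm15446 fell to 0.0716 ± 0.0441 from 3.31 ± 0.449 FPKM (SD, n = 3), the mitochondrial tRNA gene mt-Tg to 0.334 ± 0.290 from 53.6 ± 21.3 FPKM, and Rbp7, a retinol-binding protein gene, to 1.04 ± 0.0413 from 2.52 ± 0.388 FPKM. The non-coding RNA 1010001B22Rik was listed at 0 in all 3 P311-/- libraries and at 1.01 ± 0.287 FPKM (SD, n = 3) in old wild type. Gm8066 rose to 2.98 ± 1.23 from 0.568 ± 0.0551 FPKM (SD, n = 3). Gm15446 and 1010001B22Rik lie within 1 Mb of each other on chromosome 5. Among genes that did not pass, the rule for named genes, which takes those of smallest p in each direction that meet its other conditions, added Wdfy1 (log2 fold change 1.19, adjusted p = 0.0521), Slc25a25 (1.45, 0.149), Ddit4 (1.51, 0.175), Selenoo (0.93, 0.175) and Aspa (-1.04, 0.0796). Other genes that did not pass had a smaller p than some of these, among them mt-Tr (-4.16, adjusted p = 0.0521) and Tfrc (-1.07, 0.133).

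Without P311-/- replicate 1, which lay apart from the other 2, 1875 genes passed, 992 higher and 883 lower; without old replicate 1, 2 or 3 the count was 6, 4 or 5, and 4 genes (Nrep, Hmgb1, Tmem181b-ps and Gm15446) passed in every such fit. With voom and library quality weights, which gave P311-/- replicates 1, 2 and 3 weights of 0.213, 0.683 and 2.88, 4211 genes passed. Voom without weights gave 7, and library weights on log2 FPKM (0.270, 0.687 and 2.54) gave 2720, so the higher count came with the weights, under which replicate 3 counted most. In a fit of the 6 libraries 6 passed.

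Each list that passed in this comparison had an adjusted p of 0.902 with an estimated correlation, and fry passed none. Nuclear oxidative phosphorylation genes had a median of -0.38, with 71 of 75 members below 0 (camera adjusted p = 1.45e-16). By limma none passed over all genes, 38 had an unadjusted p under 0.05 and 21 were lower adjusted over the list alone. Uqcrb stood at 224 ± 53.4 against 392 ± 66.3 FPKM (SD, n = 3), with an adjusted p of 0.242, and Cox6c, a subunit of complex IV, had a log2 fold change of -0.93 (adjusted p = 0.242). Ribosomal protein genes had a median of -0.22 (camera adjusted p = 1.83e-10), with none called over all genes or adjusted over the list alone (27 at an unadjusted p under 0.05), and Rpl34 had a log2 fold change of -0.79 (adjusted p = 0.242). Longer genes and genes of higher GC content tended to be higher in old P311-/- than in old wild type, with Spearman correlations across 14219 genes of 0.19 and 0.40. Between old P311-/- and young wild type they were -0.11 and -0.04. With the trend removed nuclear oxidative phosphorylation genes had a median of -0.29 (camera adjusted p = 1.93e-14) and ribosomal protein genes -0.20 (6.72e-09). The reported medians of these lists lay at percentile 0 and 0.09 of 10000 random lists matched on length and GC content. The random lists drew genes independently. A list whose genes vary together reaches an extreme percentile more readily, so the percentiles cannot decide. The medians left with the trend removed argue against the trend alone for these lists. Among the mitochondrially encoded genes, of median -0.36 (camera adjusted p = 0.00352), none was called over all genes (2 at an unadjusted p under 0.05) and 1 was lower adjusted over the list alone. That list did not pass without old replicate 2 (adjusted p = 0.0537) or P311-/- replicate 1 (0.157), and with the trend with GC content and gene length removed its median was 0.18 (adjusted p = 0.893).

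Extracellular matrix genes had a median of -0.38 (camera adjusted p = 0.00149; adjusted p = 0.902 with an estimated correlation), with none called over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), and that list did not pass without P311-/- replicate 2 (adjusted p = 0.741). Col1a1 itself had a log2 fold change of -0.15 (SE 0.24, adjusted p = 0.779). The matrix list was 0.83 higher on the log2 scale in P311-/- replicate 1 than in the mean of replicates 2 and 3. Without replicate 1 its median was -0.63 (camera adjusted p = 1.80e-09, or 0.523 with an estimated correlation). TGF-beta pathway genes had a median of 0.22 (camera adjusted p = 0.0125; adjusted p = 0.902 with an estimated correlation), none was called over all genes (6 at an unadjusted p under 0.05) and 2 were higher adjusted over the list alone. Ltbp4 and Ltbp3, which bind latent TGF-beta, had log2 fold changes of 0.64 and 0.52. The list did not pass without P311-/- replicate 1 (adjusted p = 0.0627) or with the trend with GC content and gene length removed (0.125). Tgfb1, Tgfb2 and Tgfb3 had log2 fold changes of -0.06, 0.54 and 0.39 and did not pass. Atrophy and autophagy genes had a median of 0.29 (camera adjusted p = 0.0125; adjusted p = 0.902 with an estimated correlation), with none called over all genes (6 at an unadjusted p under 0.05) and 1 higher adjusted over the list alone. That list did not pass without P311-/- replicate 2 (adjusted p = 0.168) or 3 (0.0539). Without replicate 1 its median was 0.44 (camera adjusted p = 2.30e-05, or 0.136 with an estimated correlation).

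Some immune lists were lower by camera, and these differed among the P311-/- libraries. T and NK cell genes had a median of -0.56 (20 genes, camera adjusted p = 0.0118), macrophage genes -0.41 (24 genes, adjusted p = 0.0116) and cytokines and chemokines -0.45 (21 genes, adjusted p = 0.0225). Cell cycle genes had a median of -0.29 (35 genes, adjusted p = 0.0125). Each of the 4 had an adjusted p of 0.902 with an estimated correlation. The lists of MHC class II (median -0.31, adjusted p = 0.0801), dendritic and mast cells (-0.27, 0.321), neutrophils (-0.32, 0.785), interferon response (-0.07, 0.470), complement (0.12, 0.649) and B and plasma cells (0.08, 0.971) did not pass. In the 4 lists that passed 0 members passed limma over all genes or adjusted over the list alone, beside 4, 6, 3 and 1 at an unadjusted p under 0.05. The granzyme gene Gzma had a log2 fold change of -1.49 (adjusted p = 0.243), Il1b -2.65 (adjusted p = 0.253) and Adgre1 -0.74 (adjusted p = 0.291). In P311-/- replicate 1, T and NK cell genes were 1.53, cytokines 1.24, cell cycle genes 1.07 and macrophage genes 0.82 higher on the log2 scale than in the mean of replicates 2 and 3. Without that replicate the medians were -1.12 for T and NK cells, -0.84 for macrophages, -0.87 for cytokines and -0.57 for the cell cycle. Without P311-/- replicate 2 the 4 adjusted p were 0.305, 0.305, 0.342 and 0.741 in the same order. Without P311-/- replicate 3 they were 0.0799 for T and NK cells and 0.0539 for cytokines and the cell cycle. Without old replicate 1 they were 0.0859 for T and NK cells, 0.301 for macrophages and 0.489 for cytokines, and without old replicate 3 it was 0.147 for the cell cycle. Cytokines also did not pass with the trend with GC content and gene length removed (adjusted p = 0.119).

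The satellite cell, myogenic and embryonic fibre lists did not pass between old P311-/- and old wild type, with medians of -0.03, 0.06 and -0.23 (camera adjusted p = 0.830, 0.159 and 0.695). Pax7 had a log2 fold change of 0.26 (adjusted p = 0.603), Myod1 0.06 (0.897), Myog 0.01 (0.992), Myh3 0.75 (0.437) and Myh4 0.22 (0.667). B and plasma cell genes had a median of 0.08 and a mean of -0.06, and immediate early genes 0.04 and -0.07; neither list passed.

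**Figure D4:**
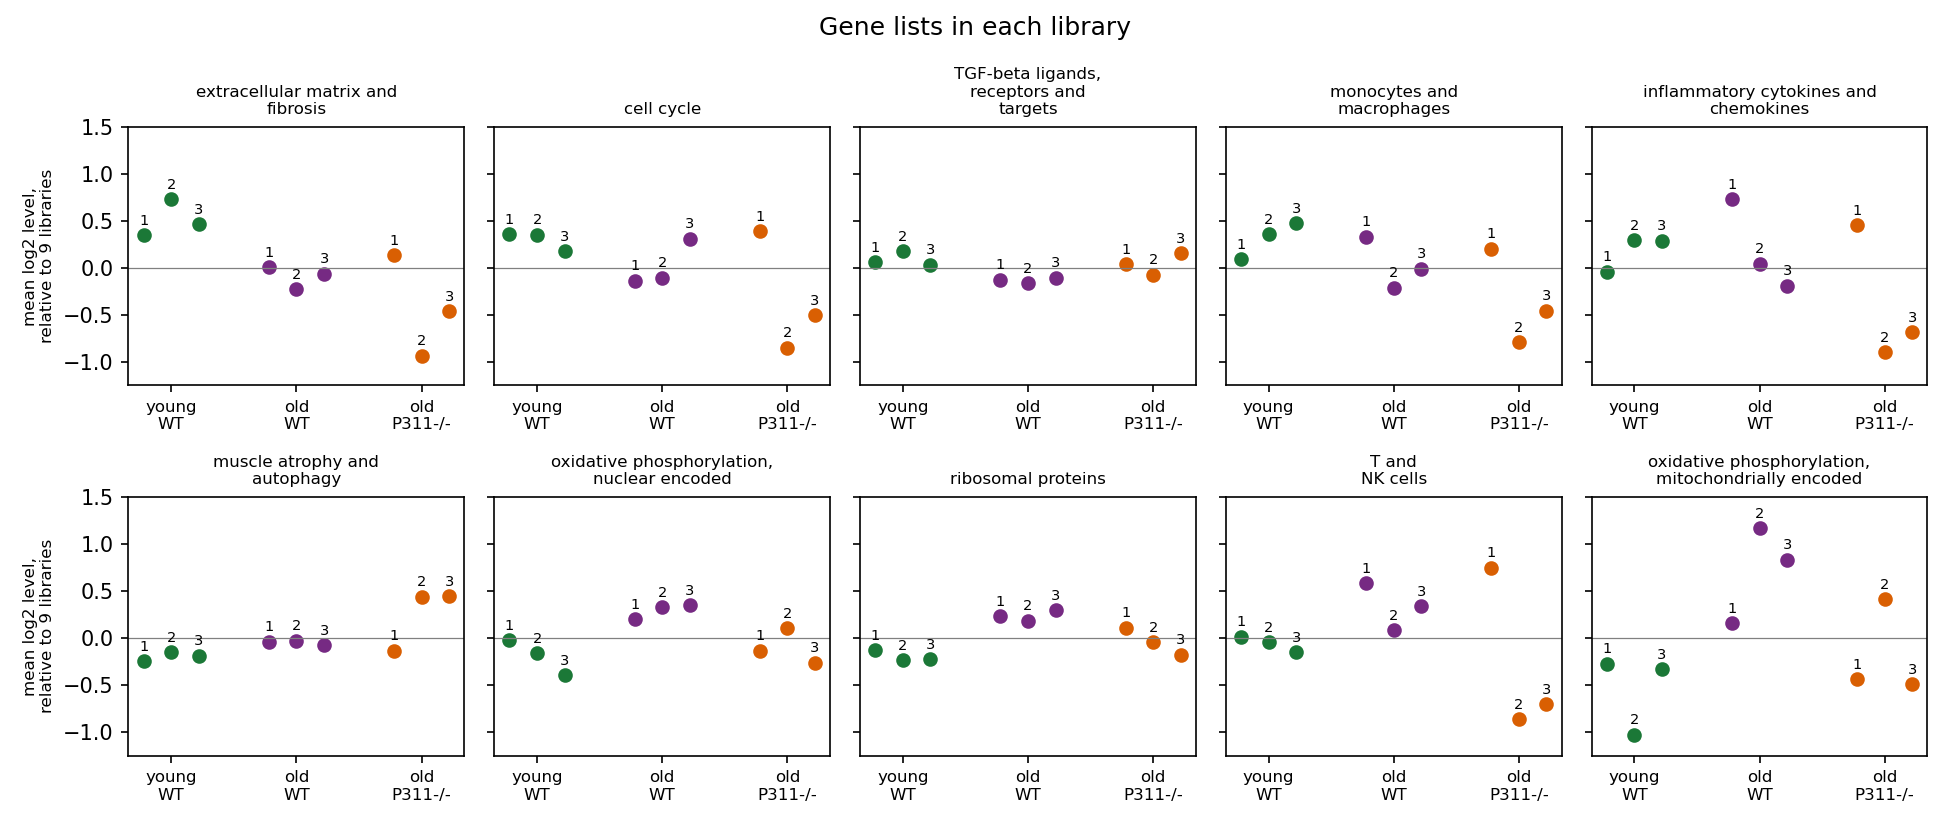
Mean log2 expression of selected gene lists in each of the 9 libraries, 1 point per library, relative to the mean of all libraries. In old P311-/- replicate 1, T and NK cell genes lie 1.53 and matrix genes 0.83 above the mean of replicates 2 and 3.

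Old P311-/- muscle was also compared with young wild type, which asks how far the old knockout lies from young muscle. Car3 (ENSMUSG00000027559, chromosome 3, 14863512 to 14872523), a carbonic anhydrase abundant in muscle, stood at 1616 ± 382 FPKM (SD, n = 3) in P311-/- and 310 ± 77.6 FPKM (SD, n = 3) in young muscle. Dbp stood at 30.9 ± 5.41 against 6.34 ± 2.13 FPKM (SD, n = 3). Nmrk2, a nicotinamide riboside kinase of muscle, was lower, at 39.1 ± 6.49 against 108 ± 14.3 FPKM (SD, n = 3). The collagen chaperone Serpinh1 stood at 55.9 ± 16.4 against 144 ± 8.71 FPKM (SD, n = 3), and the matrix protein gene Sparc at 228 ± 69.9 against 514 ± 13.2 FPKM (SD, n = 3).

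With limma, 57 of 14233 genes passed, 22 higher and 35 lower, and 43 changed at least 2-fold. The values of the groups did not overlap for 23.5% of genes, where chance gives 10% on average over splits, with the same limit. Car3 rose by 2.38 (SE 0.22, adjusted p = 0.00423), Dbp by 2.31 (SE 0.33, adjusted p = 0.0308), Sh3rf2 (chromosome 18, 42053667 to 42158960, within 20 Mb of Nrep) by 2.198, the signalling protein gene Wnt4 by 2.02 and Ctxn3 by 1.88 on the log2 scale. Irx3os fell by 1.84, Col8a2, a collagen chain, by 1.58, Sgms2, a sphingomyelin synthase, by 1.51 and Nmrk2 by 1.46 (SE 0.18, adjusted p = 0.0155). The count was 15, 10 and 4 without young replicates 1, 2 and 3, 37, 11 and 21 without old replicates 1, 2 and 3 and 2785, 10 and 8 without P311-/- replicates 1, 2 and 3, and 4 genes (Car3, Nrep, Tmem181b-ps and Gm15446) passed in every such fit. It was 34 under total-count scaling, 23 with no filter, 12 in a fit of the 6 libraries, 87 with a pseudocount of 1 and 4422 with voom and library quality weights (139 with voom alone and 3173 with library weights alone).

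Each of the 14 lists that passed against young wild type had an adjusted p of 0.783 with an estimated correlation, and fry passed none. Of 37 matrix genes, 2 fell over all genes and 32 adjusted over the list alone (median -0.87, camera adjusted p = 9.49e-20). These 2 were Serpinh1 and Sparc, and Col1a1 had a log2 fold change of -1.19 (adjusted p = 0.0648). In the other 13 lists 0 members passed limma over all genes, where 14 of the fibroblast markers and 12 of the macrophage genes had an unadjusted p under 0.05. Adjusted over the list alone, 11 of 20 fibroblast markers fell (median -0.64, camera adjusted p = 9.45e-07), as did 1 macrophage gene (median -0.77, adjusted p = 8.00e-06), 1 cell cycle gene (median -0.59, adjusted p = 1.01e-05), 4 genes of MHC class II presentation (median -0.58, adjusted p = 0.00480) and 4 tenocyte genes (median -0.72, adjusted p = 0.00556). The macrophage gene Adgre1 had a log2 fold change of -1.54 (adjusted p = 0.0624) and the tenocyte gene Tnmd -1.52 (adjusted p = 0.0561). Interferon response (median -0.46, adjusted p = 0.001003), complement (-0.24, 0.0334) and cytokines (-0.47, 0.0200) were lower too, with 0, 0 and 2 members called adjusted over the list alone.

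The lists that were higher, each with an adjusted p of 0.783 with an estimated correlation, were fatty acid oxidation (median 0.32, camera adjusted p = 0.000276), atrophy and autophagy (0.44, 0.000199), ribosomal proteins (0.17, 0.001003), slow fibre genes (0.44, 0.0247) and neuromuscular junction genes (0.20, 0.0176). Adjusted over the list alone, 1, 2, 0, 3 and 1 of their members rose, and 1 slow fibre gene fell. Cd36 had a log2 fold change of 0.92 (adjusted p = 0.0561), the atrophy genes Mstn and Klf15 1.14 (0.0769) and 1.27 (0.0804), Sln 1.57 (0.0850) and Gadd45a 1.77 (0.0631). Without P311-/- replicate 1 the lists of ribosomal proteins (adjusted p = 0.178), slow fibre genes (0.0986) and tenocytes (0.154) did not pass. Without replicate 2 of that group interferon response (0.217), cytokines (0.217) and complement (0.245) did not pass, and without replicate 3 interferon response (0.0687), cytokines (0.0624) and slow fibre genes (0.134) did not pass. Without young replicate 3, slow fibre genes (0.123), complement (0.0682) and neuromuscular junction genes (0.0626) did not pass. Under total-count scaling complement (0.0805), cytokines (0.0771) and ribosomal proteins (0.0725) did not pass, nor did complement with a filter at 1 CPM (0.0564).

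Nuclear oxidative phosphorylation genes (median 0.11, camera adjusted p = 0.0998), satellite cell genes (-0.11, 0.342), myogenic genes (0.16, 0.213), embryonic fibre genes (0.08, 0.454) and TGF-beta pathway genes (-0.10, 0.714) did not pass against young wild type. Pax7 had a log2 fold change of -0.33 (adjusted p = 0.448), Myod1 -0.17 (0.628), Myog -0.38 (0.612), Myh3 -0.04 (0.972), Myh4 0.20 (0.664), Tgfb1 -0.24 (0.581), Tgfb2 0.17 (0.632) and Tgfb3 0.05 (0.907). The pericyte list, which did not pass, had a median of 0.04 and a mean of -0.05.

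The 768 genes that changed with age were followed in old P311-/- muscle, to ask whether the knockout lay nearer to young muscle. Of these genes, 3 were called in the opposite direction between old P311-/- and old wild type and 0 in the same direction by limma. Hmgb1 and Klra7 were higher in old than young wild type and lower in P311-/-, and Gm8066 was lower and then higher. Against young wild type, P311-/- muscle had log2 fold changes of -0.73 for Hmgb1 (limma adjusted p = 0.0518), -0.99 for Klra7 (0.0801) and -0.61 for Gm8066 (0.213). None of these passed. The P311-/- means of Hmgb1 and Klra7 lay below the young means (5.93 against 9.89 and 0.564 against 1.22 FPKM). That of Gm8066 lay between old and young wild type. In 100 simulations with no difference between any groups, the same libraries shared by the comparisons gave a mean of 4.64 genes in the opposite direction (1 to 9), a range that holds the 3. The simulations treated genes as independent and took as many genes as were called, ranked by difference over noise. Of the 768, 30 were called in the same direction between old P311-/- and young wild type, where the simulations gave a mean of 20.4 (14 to 28).

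Genes called higher with age had a median log2 fold change of 0.80 in old wild type and 0.40 in old P311-/- muscle, both against young. The second was 49.6% of the first, and the simulations gave a mean of 49.6% (42.3% to 55.3%). In the simulations no gene differed with age, so every age call there was false. They do not show how much would be kept if the age changes were real and the knockout had no effect. The match therefore decides nothing about the knockout, and the same limit holds for the simulated counts and signs. Genes called lower had -0.79 and -0.49, or 61.2%, where the simulations gave 49.9% (43.5% to 56.8%). Opposite signs in the comparisons of old with young wild type and of P311-/- with old wild type were found for 698 of the 768 genes (90.9%), and in the simulations for 90.4% (88.3% to 92.6%). That share was 73.2% of 1755 genes without P311-/- replicate 1 and 79.2% of 3001 with voom and library quality weights, settings that were not simulated.

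Across all genes tested the fold changes of these comparisons correlated at -0.44, against -0.50 in the simulations, with a covariance of -0.10 against -0.04, and genes are not independent replicates. The covariance was -0.0563 with the trend with GC content and gene length removed, -0.0492 with a pseudocount of 1, -0.153 with no filter, -0.158 with voom and library quality weights and -0.153 without old replicate 1. With separate old wild-type libraries in each comparison (1 in the first and the other 2 in the second, or the reverse), which was chosen after the values were seen, the covariance was -0.0809 to -0.0314 and the correlation -0.29 to -0.11 over the 6 arrangements. Without P311-/- replicate 1 the covariance was -0.0792 to -0.0268. No library is shared there, but the arrangements share libraries with each other and no p was computed, and any difference of the old wild-type group from both other groups, whatever its cause, would give a value below 0. The count of genes called in the opposite direction was 0 when any 1 of the 3 young libraries, old replicate 2 or old replicate 3 was left out. It was 367 without P311-/- replicate 1 and 1155 with voom and library quality weights, beside 60 and 106 genes called in the same direction. The count still called against young was 2, 1 and 0 without young replicates 1, 2 and 3, 0 and 1 without old replicates 2 and 3 and 666, 3 and 2 without P311-/- replicates 1, 2 and 3.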

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

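Pseudocounts of 1 and 0.01, TMM scaling, voom without weights, library weights on log2 FPKM and removal of the trend with GC content and gene length were chosen after the data were seen; the other alternatives were planned. The planned edgeR and DESeq2 tests were not run on the recovered reads, so the counts they would give are unknown. The planned median-of-ratios factors are the deposited scaling. For single named genes, 3824 of 4639 values kept their direction and side of the threshold, 511 no longer passed, 277 newly passed and 27 reversed; for single lists 465 of 578 kept their call. The excess of between-group over within-group distance stayed above 0 in all 24 alternative values, at 12.3 to 17.7, 4.32 to 8.24 and 8.73 to 13.7 in the order below, and its exact test cannot pass with 3 libraries against 3. Nrep kept its direction and call against both wild-type groups, and 4 of its 60 values reversed, all for old against young wild type. Unless a reason is given, the cause was not tested.

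Counts of genes are given for old against young wild type (768), old P311-/- against old wild type (10) and old P311-/- against young wild type (57). With no filter, where more genes were tested, the first and last were 5 and 23. Total-count scaling gave 346 and 34 with a median of all genes of -0.12 and -0.13 on the log2 scale, against 0.00496 and 0.0141 as reported. Voom with library quality weights gave 3001, 4211 and 4422, voom without weights 1005, 7 and 139, and library weights on log2 FPKM 2290, 2720 and 3173, so the higher counts came mostly with the weights. Fits of the 6 libraries compared gave 1653, 6 and 12. A minimum fold of 2 gave 219 for the first, and a pseudocount of 1 gave 87 for the last. With the trend with GC content and gene length removed the first was 13. The replicate number as a block gave 0, 4 and 5 with limma, beside 3386, 1997 and 2757 at an unadjusted p under 0.05. The numbers did not pair the libraries, since deviations of libraries with the same number correlated across genes at -0.10 to 0.15 and those with other numbers at -0.16 to 0.21, and a library correlated best with its own number in 4 of 18 cases. Leaving out single libraries gave 0 to 1755, 4 to 1875 and 4 to 2785.

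Lists that passed numbered 10, 10 and 14. They were 0, 0 and 0 with an estimated correlation, 0 for the second with an estimated correlation and without P311-/- replicate 1 (chosen after the data were seen), and 1, 0 and 0 with fry. Leaving out single libraries gave 8 to 13, 6 to 12 and 11 to 16. With camera at the preset correlation, 6, 2 and 7 of the lists kept their call in all 15 other settings run for lists, which were total-count and TMM scaling, the filter at 1 CPM, removal of the trend, the replicate block, fits of the 6 libraries compared and leaving out each of the 9 libraries. None kept it with an estimated correlation.

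Age-changed genes called in the opposite direction in old P311-/- muscle numbered 0 with no filter, 1155 with voom and library quality weights, 0 with the replicate block, 1 with the trend removed and 0 to 367 without single libraries. Those still called against young numbered 16 under total-count scaling, 2 with no filter, 1319 with voom and library quality weights, 0 with the replicate block, 51 with a pseudocount of 1, 3 with the trend removed and 0 to 666 without single libraries.

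None of the values that reversed had passed, and all are log2 fold changes. For old against young wild type, Nrep was -0.10 under total-count scaling, -0.29 with the trend removed and -0.0693 to 0.148 without single libraries. Myh4 was 0.000803 with TMM, 0.0185 with upper-quartile scaling, 0.23 with the trend removed and -0.17 to 0.12 without single libraries. With the trend removed Tgfb1 was 0.0222 and Itga7 was 0.0350. For old P311-/- against old wild type, Myog was -6.82e-05 under total-count scaling, -0.00108 with the trend removed and -0.28 to 0.41 without single libraries. Myod1 was -0.0549 with the trend removed and -0.0946 to 0.24 without single libraries, Col1a1 -0.438 to 0.0837 and Tgfb1 -0.26 to 0.11. For old P311-/- against young wild type, Myh3 was 0.00629 with upper-quartile scaling, 0.28 with voom and library quality weights, 0.0170 with the trend removed and -0.36 to 0.44 without single libraries. Tgfb3 was -0.10 under total-count scaling and -0.0872 to 0.223 without single libraries, and Myog was -0.635 to 0.0119. Depth, from 14222204 to 31910890 reads per library, limits genes of low expression, and changes of 2-fold were recovered in 54% to 65% of simulated genes. Those simulations held independent genes and no library apart from its group.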

Other observations

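The tests of the region around Nrep, of neighbouring genes and of P311-/- replicate 1 were chosen after the result was seen; the others were planned before their result was seen. Of 13 clock genes looked at beside Dbp, 3 passed in old against young wild type, 1 in old P311-/- against young wild type and none in old P311-/- against old wild type. Arntl, the partner of CLOCK, fell by 0.89 on the log2 scale in old against young wild type (limma adjusted p = 0.0367) and by 1.26 in old P311-/- against young wild type (adjusted p = 0.0373). In old against young wild type Nr1d2 rose by 0.79 (adjusted p = 0.0337) and Nfil3 fell by 0.71 (adjusted p = 0.0472), and Npas2 had a log2 fold change of -1.11 (adjusted p = 0.0536). Per1, in phase with Dbp, had a log2 fold change of -0.39 in old against young wild type (adjusted p = 0.534). It stood at 6.93, 18.4 and 17.8 FPKM in the P311-/- libraries and at 2.58, 3.80 and 4.93 FPKM in the old wild-type libraries, with a log2 fold change of 1.82 (adjusted p = 0.215).

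Without P311-/- replicate 1, the comparison of old P311-/- with old wild type also held lower interferon response genes (median log2 fold change -0.64, camera adjusted p = 1.13e-07) and MHC class II genes (-0.63, adjusted p = 0.000328), and higher fast fibre genes (0.39, adjusted p = 0.00417) and fatty acid oxidation genes (0.21, adjusted p = 0.0387). With an estimated correlation none of them passed (adjusted p = 0.540, 0.516, 0.744 and 0.801). That fit held 2 P311-/- libraries. With all 3, the medians were -0.07 (adjusted p = 0.470), -0.31 (0.0801), 0.15 (0.159) and 0.04 (0.953).

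In the splits of 6 libraries into 3 and 3, 1 of 10 splits, the real one, gave as many called genes in each comparison. The real counts were 768, 10 and 57 and the highest of the other splits 0, 1 and 1. At an unadjusted p under 0.05 the real split gave 3748, 2296 and 3051 genes by limma. The highest of the other splits gave 816, 2704 and 2138. For old P311-/- against old wild type the real split was thus not the highest. The 10 splits are too few for a share under 0.05.

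Ribosomal protein and nuclear oxidative phosphorylation genes were higher as lists in old than young wild type by camera at the preset correlation. With an estimated correlation neither list passed (camera adjusted p = 0.956 for each), and 21 of 74 and 15 of 75 members passed limma. A trend with gene length and GC content alone is argued against by the medians of 0.35 and 0.32 left when it was removed. The list medians of 0.43 and 0.43 lay at percentile 100 and percentile 100 of 10000 random lists matched on both, whose medians were 0.11 and 0.14. The random lists drew genes independently. A list whose genes vary together reaches an extreme percentile more readily, so these percentiles cannot decide. Scaling set by a few abundant transcripts is argued against as well, since the lowest medians over TMM, total-count and upper-quartile scaling were 0.299 and 0.296. The trend may still account for part of the difference, because the medians were lower with it removed. Age, the difference the design names, stays open and was not tested apart from any other difference between the groups.

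Between old P311-/- and old wild type 10 genes were called. Other-strain DNA beside the deleted gene is not where the other 9 calls lie, as 9 of 9 are on other chromosomes or the mitochondrial genome; whether it acts on genes elsewhere or nearby stays open, since the 0 calls within 20 Mb, where 167 of 14233 genes were tested, are too few to decide, and Sh3rf2, called against young wild type, and Gm10268 (log2 fold change -2.83, adjusted p = 0.102 against old wild type) lie there. Uneven immune and matrix content of the P311-/- libraries stays open: the range among them was a median of 0.167 of the group difference, but a gene passes only when that range is small, so the bound set for this test could decide nothing. A strain or copy-number difference elsewhere remains a candidate explanation for some of them. The 50 nuclear genes with p under 0.001 held 11 pairs within 1 Mb of each other, 6 of them among Klra genes. Random sets held a median of 2 pairs, and 1 of 10000 sets held as many. These sets drew genes independently, so neighbours that vary together give extra pairs whatever the cause. Klra7 is a receptor of NK cells, and T and NK cell genes had a median of -0.56 here. The Klra pairs may thus follow NK cell RNA instead, which was not tested. Klra7 itself did not follow the T and NK cell list among the P311-/- libraries. Relative to the mean of all libraries, that list stood at 0.74, -0.87 and -0.71 on the log2 scale in replicates 1, 2 and 3. In old wild type it stood at 0.09 to 0.58. Klra7 stood at 0.564 ± 0.0890 FPKM (SD, n = 3) in P311-/-. The other Klra genes were not compared by library. Nnt, a strain marker, stood at 0 to 0.0997 FPKM in all 9 libraries and did not separate the groups, but 1 marker does not cover the genome. An effect of P311 loss on these genes is not excluded by these values.

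P311-/- replicate 1 held more RNA of immune, cell cycle and matrix genes than replicates 2 and 3. A wrong genotype label is argued against, because its Nrep value lay 49.0 FPKM below the lowest wild-type library, where the SD of the wild-type libraries was 8.29. Lower depth is argued against, as it had 25652596 reads and replicate 2 had 20475248. A lower share of muscle fibre RNA alone is argued against, since the median difference of 5 immune cell lists (0.30 to 2.34) exceeded that of 8 other cell type lists (-0.76 to 0.96) by 0.613 on the log2 scale, and T and NK cells exceeded endothelial cells by 1.497. The 2 ranges overlap. A lower fibre share may still be part of it. Fast fibre, slow fibre and fatty acid oxidation genes differed by -0.50, -0.39 and -0.57 in replicate 1. Nuclear oxidative phosphorylation and embryonic fibre genes differed by -0.05 and 0.46. Over all tested genes, replicate 1 lay at distances of 59.62 to 69.96 from the old wild-type libraries. Replicates 2 and 3 lay at 78.63 to 90.58 from them, and the old wild-type libraries at 59.25 to 63.67 from each other. Which of the P311-/- libraries are the unusual ones therefore stays open. A different stage or extent of injury in replicate 1, or in replicates 2 and 3, may account for the difference and was not tested.

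A further hypothesis is that the groups were collected at different phases of the daily clock. If so, genes in phase with Dbp would be higher and those of opposite phase lower. In old against young wild type the opposite-phase genes Npas2, Clock and Nfil3 had a median log2 fold change of -0.71 and 9 genes in phase with Dbp had 0.55, which is consistent with a shift of phase. An effect of age on the clock would give the same values, and the times of collection are not given in the sources used here. In old P311-/- against young wild type the medians were -0.37 and 1.14.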
